A study of Mus musculus with 10 samples.

How the data were processed

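Denervated and contralateral TA muscle of CD1 mice aged 3 months were compared on 10 spotted 2-colour arrays, 2 of opposite labelling at each of 5 time points. Per the labels, 8 µg of total RNA was reverse transcribed with an oligo-dT primer and a dye-labelled nucleotide, and both muscles were hybridised together. Per the labels, the authors quantified images with QuantArray and applied global and lowess normalization to each spot with SNOMAD. The deposited values are log2 ratios of the normalized intensities, and per the labels a positive value means more RNA in denervated muscle on all 10 arrays, so no sign was turned. Background correction, spot filters and software versions are not given in the sources used here. Intensities were not used here, so signal over background is unknown for every value. Lowess normalization centres each array, so a ratio is relative to the bulk of the spots on its array. Medians over the probes ran from -0.15 (day 14, first labelling) to 0.09 (day 7, first labelling), and no value was missing. Scale and direction come from the labels, and a centring step beyond the normalization is not stated.

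The platform annotation names 388 of the 9216 spots. All 97 named probes recurred at 4 fixed offsets within 1 of 16 print blocks, and this layout was applied to every spot, which gave 2304 probes of 4 spots. That the unnamed spots share the layout is an inference. A probe's value was the median of its 4 spots, a choice made after the layout was seen. On each array 1 value recurred to the last digit, in 91 to 745 spots, while the next commonest value was held by at most 18. What it stands for is not given in the sources used here. These spots were kept, and an alternative chosen after seeing the data left them out and needed at least 2 other spots of a probe on every array, which kept 2058 features and all named genes but Insr. Of the probes, 93 had 1 gene symbol, 4 had several and were left unnamed, and 2207 had none, which makes them unnamed here and not without a gene. Symbols were updated through the Entrez identifier in a mouse RefSeq gene table (assembly GRCm38.p6). For 9 genes the identifier was not in that table and the older name was kept. Probes of a gene were averaged, which left 89 genes, and unnamed probes are called by their lowest spot number.

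The 2 arrays of a time point are a labelling swap and counted as 1 replicate. Before the data were examined, 3 tests with limma (version 3.58.1 in R 4.3.3) on the time-point means were fixed. They were the mean of days 1 to 14 against 0, the slope on log2(day + 1) over 5 time points, and days 7 and 14 minus days 1 and 3. All were two-sided, with Benjamini-Hochberg adjustment over 2300 features and a threshold of 0.05. A rule of size per time point and gene list tests for lists with at least 5 measured members were also fixed then. No list reached 5, so list tests were not run. The array-level fit, with limma on the 10 arrays as separate samples and 5 residual degrees of freedom, had been planned as an alternative to the rule of size. It was given its place in the report after the 3 tests had returned 0 calls. Its p-values take the arrays of a swap as separate samples and measure the spread between them alone. Differences between days and from time 0 were contrasts of the same fit.

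The rule for named genes took the 10 highest and 10 lowest means with the same sign on all 8 arrays, the 5 steepest slopes each way with an unadjusted p under 0.05, the 5 highest and 5 lowest ratios per time point with the same sign on both arrays, up to 4 members per list, and 24 fixed genes. It picked mostly unnamed probes, so it was also applied within the 89 named genes, once the annotation was known. Named genes past the array-level threshold, the late against early genes with an unadjusted p under 0.05 and spot_227 were added after their values were seen.

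The fits were tested on simulated data with 100 features changed by a log2 ratio of 1 and 100 by 2. The array-level fit recovered 61% and 78% of them at 1 time point, with 9 false calls there and 0 at an unchanged time point, and the mean fit made 7 false calls. All simulated values were independent normal draws, with no labelling effect, no repeated values and no link between the arrays of a time point. These figures therefore do not give the recovery or the false calls of the array-level fit on the real arrays. Intervals for correlations are 95% bootstrap intervals from 1000 resamples of features, which are not independent, so they are too narrow. Alternatives covered the random block for time point, the labelling orientation as a block, time 0 subtraction, centring, scaling, spot summaries, spot agreement, repeated spot values, print-block centring and left-out arrays and days. The random block, the orientation block and scaling were run for the 3 planned tests alone. They were not run for the array-level calls or the differences between days. With 1 array left out, its time point rests on the other array and is tested with less power. A call lost there does not by itself show that the ratio rested on 1 array. Figures were drawn with matplotlib 3.10.9. The number of arrays limits the precision of all values.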

Results

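RNA from the denervated TA muscle of CD1 mice aged 3 months was compared with RNA from the contralateral TA muscle on the same 2-colour spotted array. TA is a fast-twitch hindlimb muscle that atrophies when its nerve supply is lost. The 10 arrays covered time 0 and days 1, 3, 7 and 14 after denervation, with 2 arrays of opposite labelling at each of the 5 time points. Each array held 9216 spots, read here as 2304 probes spotted 4 times each and summarised as 2300 features. Of these, 89 were genes with a single symbol and 2207 were unnamed probes, so the gene-level account covers a small part of the array. All values are log2 ratios of denervated over contralateral muscle, given as the mean ± SD of the 2 arrays of a time point. The labels do not say whether both arrays shared extracts or how many animals they covered, so these SDs and the p-values over arrays measure the spread between arrays, which may be technical.

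Over days 1 to 14, the question was which transcripts differed between denervated and contralateral muscle throughout. Mef2a, a transcription factor of muscle differentiation, was the single named gene with a higher value in denervated muscle on all 8 arrays, at a mean log2 ratio of 0.57 ± 0.25 (SD, n = 4 time points). With the mean of the 4 spots in place of their median it was 0.74, and its spots spanned more than 2 log2 units on at least 1 array. Scn4b, which encodes the beta-4 subunit of voltage-gated sodium channels, averaged -0.87 ± 0.65 (SD, n = 4), with day 1 at 0.10 and each later day below -1. No named gene was lower on all 8 arrays. Over all features, 48 were higher and 89 were lower on all 8 arrays, against 8.98 each way by chance for independent arrays. The arrays of a time point are not independent, so that chance value is a lower limit. Among the unnamed probes, spot_6412 averaged 2.96 and spot_4134 averaged -1.87. None of these passed the limma test on the 4 time-point means, in which 0 of 2300 features had an adjusted p under 0.05. The smallest adjusted p was 0.525, shared by many features, among them Mef2a, Scn4b, Ssh2, Sbno1, Smc5, Nt5dc2 and Rn28s1. In that fit 193 features had an unadjusted p under 0.05, where chance gives 115. In simulated data of the same size, the fit recovered 59% of 100 features changed by a log2 ratio of 1 at every time point and 88% of those changed by 2. These shares do not hold for a feature that changed only after day 1, such as Scn4b, whose time course adds to its spread in this fit.

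Scn4b was the named gene that separated denervated from contralateral muscle on each of days 3, 7 and 14. It fell to -1.18 ± 0.07 at day 3, -1.09 ± 0.13 at day 7 and -1.30 ± 0.01 at day 14 (SD, n = 2 arrays each), which are 0.441, 0.470 and 0.406 times the contralateral level. It stood at -0.07 ± 0.01 at time 0 and 0.10 ± 0.09 at day 1. Its 2 probes gave -1.08 and -1.28 at day 3, -0.98 and -1.20 at day 7, and -1.37 and -1.22 at day 14. In a limma fit with the 10 arrays as separate samples, the adjusted p for Scn4b was 0.00240, 0.00294 and 0.00110 on these days. These 3 calls held when either array of the day was left out and when time 0 was subtracted, which gave -1.11, -1.02 and -1.23.

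At day 3, 4 of the 89 named genes passed the array-level test, with 3 higher and 1 lower. Larp4b, a La-related RNA-binding protein, rose by 0.65 ± 0.14, Pcdh19, a protocadherin, by 0.63 ± 0.27 and Tmem263 by 0.45 ± 0.12 (adjusted p = 0.0468, 0.0419 and 0.0491). Scn4b was the gene that fell. Gclm, the modifier subunit of the enzyme that starts glutathione synthesis, stood at 0.64 ± 0.20 and Gnas, the stimulatory G protein alpha subunit, at -0.66 ± 0.06, and neither passed (adjusted p = 0.0696 and 0.0590). Tgoln1 (0.55), Arf6 (0.55), Bckdk (-0.55), Zbtb16 (-0.63) and Sbno1 (-0.53) completed the named genes with the largest ratios and did not pass. Over all features 183 passed, 55 higher and 128 lower, and 609 had an unadjusted p under 0.05. Without the first or the reverse labelling of day 3, Larp4b stood at 0.55 and 0.75, Pcdh19 at 0.44 and 0.81 and Tmem263 at 0.36 and 0.54. These calls were lost, in fits with 1 array left at the day and so less power. Larp4b, Pcdh19 and Tmem263 also did not pass with print blocks centred (adjusted p from 0.0829 to 0.156), arrays centred (0.0508 to 0.0798) or the mean of the 4 spots (0.0515 to 0.0764). Tmem263 did not pass with robust eBayes (adjusted p = 0.0540). The total was 36 without the first labelling and 53 without the reverse labelling, and 1 of the 4 named calls (Scn4b) held without either.

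At day 7, 5 named genes passed, with Mef2a higher and 4 genes lower. Mef2a rose by 0.92 ± 0.10 (1.89 times the contralateral level, adjusted p = 0.0368). Trdn, the triadin that anchors calsequestrin in the junctional sarcoplasmic reticulum, stood at -0.65 ± 0.13 and Ssh2, a cofilin phosphatase, at -0.60 ± 0.16 (adjusted p = 0.0160 and 0.0195). The uncharacterised 2010012P19Rik stood at -0.86 ± 0.16 (adjusted p = 0.0189), and Scn4b was the lowest of those that passed. The 3 Trdn probes differed, with -1.06 and -0.88 from 1 sequence record and -0.01 from another, so the average of -0.65 describes neither record. The largest named ratios came from single arrays. Gm6225 averaged 3.72 from 7.42 and 0.02, Nt5dc2 2.12 from 3.91 and 0.32, and Insr, the insulin receptor, 2.00 from 3.52 and 0.49. Mthfsl (1.93 ± 1.40), Smc5 (-1.32 ± 0.14), Chek1 (-0.71 ± 0.13) and Zbtb16 (-0.67 ± 0.67) also did not pass. Over all features 267 passed, 102 higher and 165 lower, and 688 had an unadjusted p under 0.05. Without the first labelling 85 passed, and without the reverse labelling 168 passed, of which 107 were higher and 61 lower, so the majority turned. Without the first or the reverse labelling, Mef2a stood at 0.85 and 0.99, Trdn at -0.74 and -0.56, Ssh2 at -0.72 and -0.49 and 2010012P19Rik at -0.75 and -0.97. These calls were lost, in fits with 1 array left at the day and so less power. Mef2a also lost the call with time 0 subtracted, print blocks centred or the mean of the 4 spots (adjusted p = 0.0996, 0.0692 and 0.178), at ratios of 0.89, 0.61 and 0.93. Trdn lost it with the mean of the 4 spots (-0.67, adjusted p = 0.0581) or with repeated spot values left out (-0.65, adjusted p = 0.0600). Restricted to probes whose 4 spots spanned at most 2 log2 units on every array, Trdn stood at -0.01 (adjusted p = 0.981), from the probe of the other record alone.

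At day 14, 13 named genes passed, 6 higher and 7 lower. Neb, the giant thin-filament protein nebulin, stood at 1.25 ± 0.32, Ddx42, an RNA helicase, at 1.07 ± 0.01 and Bckdk, the kinase that inactivates branched-chain ketoacid dehydrogenase, at 0.97 ± 0.09. Zfp948 (0.91 ± 0.06), Psmd1, a proteasome regulatory subunit (0.61 ± 0.23), and Parvb, the actin-binding beta-parvin (1.57 ± 1.25), were also higher. Nisch, the integrin-binding protein nischarin, fell by 1.40 ± 0.18, to 0.380 times the contralateral level (adjusted p = 0.00396). Slc25a4, the muscle form of the mitochondrial ADP/ATP carrier, stood at -0.68 ± 0.05, Pcdh19 at -0.65 ± 0.06, Irf1, an interferon-response transcription factor, at -0.62 ± 0.35, Ssh2 at -0.48 ± 0.06 and Tmem263 at -0.43 ± 0.01. Arhgef2 (1.76 ± 1.96) and Btaf1 (-1.31 ± 1.76) did not pass despite means of more than 1 in size. Adjusted over the named genes alone, 15 passed at day 14, 4 at day 7 and 1 at day 3. Over all features 329 passed, 201 higher and 128 lower, and 769 had an unadjusted p under 0.05. Scn4b, Nisch, Ddx42 and Zfp948 kept the call without either array. The other 9 named genes lost it without at least 1 of them, in fits with 1 array left at the day and so less power. Tmem263 also lost the call with each array centred on its median (-0.38, adjusted p = 0.0815). With print blocks centred, Slc25a4, Pcdh19, Psmd1, Tmem263, Irf1, Ssh2 and Parvb did not pass, and the total split into 231 higher and 85 lower. Tmem263 then stood at -0.05, Irf1 at -0.23 and Psmd1 at 0.39, while Slc25a4 (-0.59), Pcdh19 (-0.56), Ssh2 (-0.41) and Parvb (1.35) stayed nearer their values above. The spots of Parvb spanned more than 2 log2 units on at least 1 array, and it stood at 2.39 with the mean of the 4 spots. The day 14 total was 327 without the first labelling, with 271 higher and 56 lower, and 261 without the reverse labelling, with 124 higher and 137 lower.

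Subtracting time 0 left 2 of these 13 genes past the threshold at day 14, Scn4b at -1.23 and Nisch at -1.19 (adjusted p = 0.00821 and 0.0463). The other 11 kept their direction, some with ratios of similar or larger size, such as Ddx42 at 0.89 and Ssh2 at -0.71, and others nearer 0, such as Slc25a4 at -0.31 and Tmem263 at -0.19. The time 0 values of the 13 genes had the sign of their day 14 values in 12 cases, among them Neb at 0.62 ± 0.07 and Slc25a4 at -0.36 ± 0.18. Among the 316 unnamed features called at day 14 the share was lower, at 60.4% (191 features, exact binomial 95% interval 54.8% to 65.9%, features not being independent). Over all features 92 passed at day 14 after the subtraction, 71 higher and 21 lower, against 329 before it. A difference from time 0 has a larger standard error than the day's own ratio, since it carries the spread of both time points. A lost call therefore does not by itself show a difference already present at time 0. At days 3 and 7, 160 and 252 passed after the subtraction, of which 113 and 188 were among the 183 and 267 called before it.

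**Figure D1:**
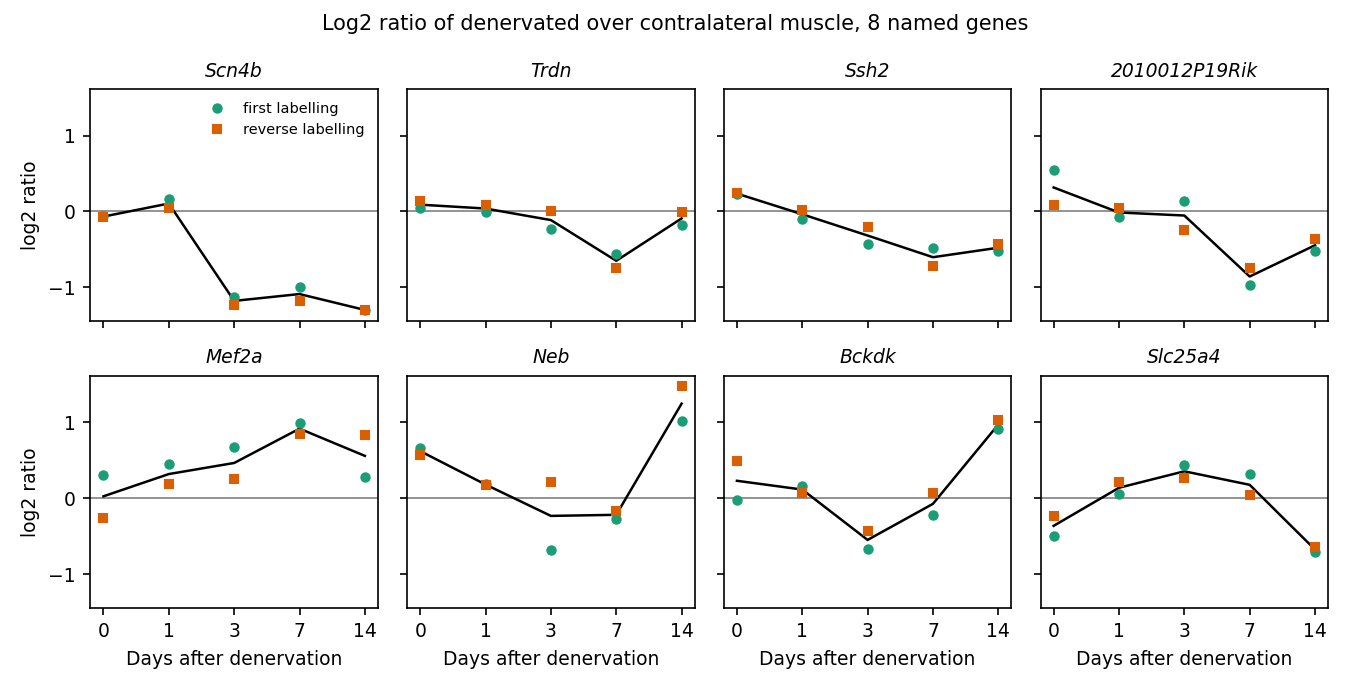
Log2 ratio of denervated over contralateral muscle (vertical axis) against days after denervation, evenly spaced (horizontal axis), for the 5 genes called at day 7 and for Neb, Bckdk and Slc25a4, called at day 14; circles and squares are the first and the reverse labelling, and the line joins their means. Scn4b lay near 0 at time 0 and day 1 and below -1 from day 3, while Neb was already at 0.62 at time 0.

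Time 0 served as the background, and day 1 was the first time point after denervation, with the lowest agreement between its 2 arrays. No named gene passed at either. The lowest and highest named ratios with the same sign on both arrays were, at time 0, Sbno1 at -0.83 ± 0.71 and Rn28s1, a ribosomal RNA gene, at 0.79 ± 0.98, and at day 1 Gm773 at -0.66 ± 0.39 and Mef2a at 0.32 ± 0.18. Other named genes under the naming rule ran up to 0.62 in size at time 0 (Neb) and to -0.41 at day 1 (Arid5b). At time 0, limma called 0 features, although 329 had an unadjusted p under 0.05. At day 1 it called 1 feature, with 45 unadjusted. That was the unnamed spot_227, at -2.16 ± 0.11 on day 1 (adjusted p = 0.0414) and at 1.04, 3.46 and 2.34 on days 3, 7 and 14. It was not called without the first or without the reverse labelling of day 1, which gave 1 other call and 0 calls.

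By the fixed rule of size, a mean log2 ratio of at least 1 with the same sign on both arrays, 67 features were large at time 0 and 60 at day 1. At day 1, 48 of the 60 met the sign condition with 1 array at a value that recurred across its spots, against 0 of the 67 at time 0. Both recurring values were negative at time 0 (-0.104 and -0.00113), and that of the first labelling of day 1 was positive (0.000226). A high ratio facing a negative value fails the sign condition. The 0 at time 0 therefore follows largely from that sign and does not show better support for those ratios. With such repeated spot values left out on the arrays of the day, 80 were large at time 0 and 14 at day 1, of 2139 and 2112 features, and 153, 193 and 256 at days 3, 7 and 14. With them left out on all 10 arrays the counts over 2058 features were 21 and 6, and 48 of the 67 at time 0 were absent because of arrays of other days. With all spots kept the counts were 157 at day 3, 197 at day 7 and 259 at day 14, with 70, 117 and 166 of them higher in denervated muscle. The majority direction depended on the setting. With spots within 2 log2 units, 24 of 89 were higher at day 7, and with time 0 subtracted 169 of 353 were higher at day 7 and 154 of 331 at day 14. At day 3 the mean of the 4 spots gave 115 of 199 higher, and 15 of 74 were higher with spots within 2 log2 units. No named gene was large at time 0 or day 1, 1 was at day 3 (Scn4b), 6 were at day 7 and 7 at day 14. Both arrays had the same sign for 62.8% of features at time 0, 51.5% at day 1, 74.5% at day 3, 71.7% at day 7 and 64.8% at day 14. With repeated spot values left out, the shares over 2058 features were 63.4%, 53.6%, 77.2%, 72.5% and 67.9%. By 1 array alone, with no sign to compare, the counts were 92 and 89 at time 0, 95 and 29 at day 1, 146 and 222 at day 3, 216 and 322 at day 7, and 447 and 432 at day 14, without the first and the reverse labelling. At day 14, 375 of the 447 and 130 of the 432 were higher. At day 1, 90 of the 95 and 3 of the 29 were higher. The day 1 count was 19 after centring each array on its median, a shift of 0.000226 and 0.000168, 11 higher and 8 lower against 52 and 8 before.

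**Figure D2:**
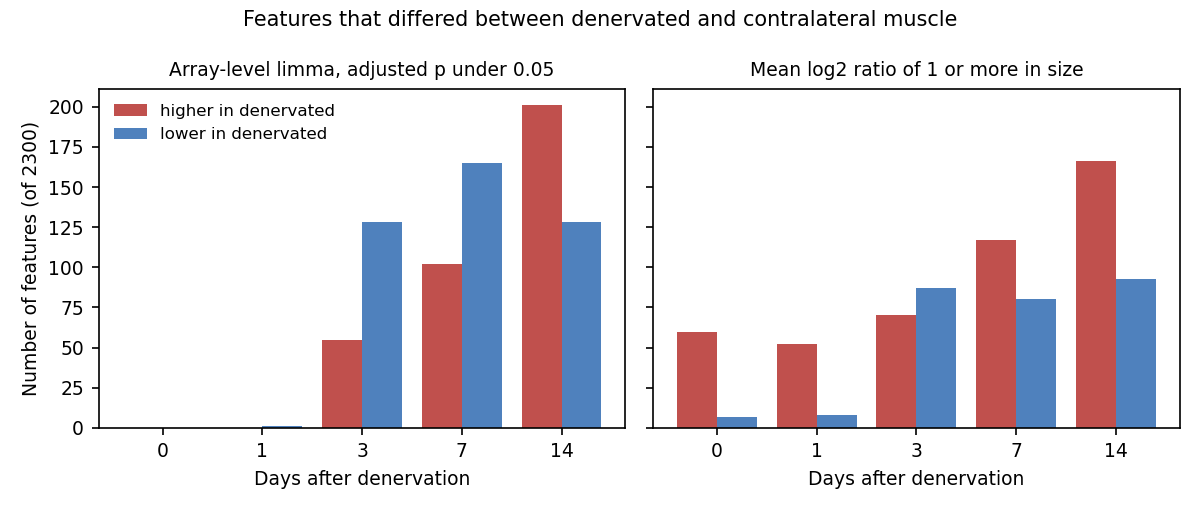
Number of the 2300 features (vertical axis) that were higher or lower in denervated muscle at each day after denervation (horizontal axis), by the array-level limma test (left) and by the rule of size (right). The test gave 0 and 1 features at time 0 and day 1 and 183, 267 and 329 at days 3, 7 and 14, while the rule of size already gave 67 at time 0.

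The features called on days 3, 7 and 14 overlapped. Of 53 features called on all 3 days, 50 had the same sign throughout, 19 higher and 31 lower, and Scn4b was the single named gene among them. Days 7 and 14 shared 62 higher and 55 lower features, where independent lists would share 8.91 and 9.18, and 3 were called in opposite directions. Days 3 and 7 shared 27 higher and 64 lower features (2.44 and 9.18 for independent lists), with 4 opposite. Days 3 and 14 shared 27 higher and 36 lower (4.81 and 7.12), with 15 opposite, among them the named genes Pcdh19 and Tmem263. Each feature's spread was shared across days in the fit, which raises such overlaps.

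The change with time after denervation was tested as a slope on log2(day + 1) over the 5 time points. Among named genes with an unadjusted p under 0.05, Scn4b had the steepest slope, at -0.37 ± 0.12 (SE) log2 units per unit, followed by Btaf1 at -0.34 ± 0.12 and Ssh2 at -0.20 ± 0.08. The Btaf1 slope rested on the first labelling, whose day 14 array gave -2.55 against -0.06 for the reverse, and was -0.09 without the first labelling and -0.60 without the reverse. Their unadjusted limma p values were 0.0226, 0.0323 and 0.0413, and none passed after adjustment (0.450, 0.460 and 0.470). No named gene had a rising slope with an unadjusted p under 0.05, although the slopes of Mthfsl (0.43) and Nt5dc2 (0.41) were larger in size than that of Scn4b. Over all features 0 passed, with a smallest adjusted p of 0.378, and 224 had an unadjusted p under 0.05. In simulated data the slope fit recovered 0% of features changed by 1 and 29% of those changed by 2 over the time course. With the 10 arrays entered separately and the time point as a random block, 52 features passed, 46 rising and 6 falling. With the labelling orientation as a replicate block as well, 32 passed, 29 rising and 3 falling. Both fits count residual degrees of freedom over the 10 arrays, while the slope varies only between the 5 time points. Their p-values are therefore likely too small, and these calls are not set above the planned test.

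Late denervation (days 7 and 14) was set against early denervation (days 1 and 3). Among named genes, Mthfsl differed by 1.56 ± 0.40 (SE), Nt5dc2 by 1.43 ± 0.51 and Chek1, a checkpoint kinase, by -0.84 ± 0.28, with unadjusted limma p of 0.0165, 0.0453 and 0.0359. Their 2 day 14 arrays had opposite signs, at -0.58 and 2.78 for Mthfsl, -0.72 and 2.49 for Nt5dc2 and -1.72 and 0.08 for Chek1. Without the first or the reverse labelling of day 14 the differences were 2.40 and 0.72 for Mthfsl, 2.23 and 0.62 for Nt5dc2, and -0.39 and -1.29 for Chek1. Scn4b differed by -0.66 (unadjusted p = 0.269), with its day 3 value of -1.18 near the later ones. No feature passed after adjustment (smallest adjusted p 0.595), and 111 had an unadjusted p under 0.05, where chance gives 115. In simulated data this comparison of 2 against 2 time points recovered 0% of changes of 1 or 2. It gave 21 calls, 10 higher and 11 lower, among the 1285 features whose 4 spots spanned at most 2 log2 units on every array.

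The gene groups fixed in advance were sparsely covered, with 8 of 29 lists having a named member and none more than 2, so no group was tested as a whole. In the calcium handling group, Trdn passed at day 7 and Jph1, a junctophilin of the triad, stood at 0.48 ± 0.21 at day 7 without passing (adjusted p = 0.0932). In the costamere and cytoskeleton group, Neb passed at day 14 and Plec, the linker plectin, ran between -0.17 and 0.05 over days 1 to 14. The single proteasome member, Psmd1, passed at day 14, at 1.52 times the contralateral level, after 0.12 ± 0.17 at day 7. The members for ubiquitin conjugation (Ube2d2a), translation (Eif4ebp2), chaperones (Hspb2), extracellular matrix (Col12a1) and redox response (Gclm) passed on no day. Ube2d2a and Eif4ebp2 stood at 0.45 and 0.30 at day 7 and at -0.45 and -0.43 at day 14, Hspb2 at -0.52 ± 0.11 at day 7 and Col12a1 at -0.12 ± 0.59 at day 14. None of the 8 cell type marker lists had a named member, so shifts in macrophages, fibroblasts, satellite cells or other cell types were not analysed here. None of the 24 genes fixed in advance, among them the atrophy ubiquitin ligases Trim63 and Fbxo32 and the acetylcholine receptor subunits, was among the named features, and they were not analysed here.

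Arrays of a time point correlated unevenly across features, which are not independent replicates. The rank correlation of the swapped arrays was 0.66 at day 3, 0.50 at day 7, 0.32 at time 0, 0.26 at day 14 and 0.10 at day 1. With repeated spot values left out they were 0.72, 0.55, 0.31, 0.40 and 0.13 in the same order. Between time points, arrays of days 3 and 7 had a mean rank correlation of 0.43, days 7 and 14 of 0.20 and days 3 and 14 of 0.08. Arrays of time 0 ran against those of days 3 and 7, at -0.22 and -0.20, and gave 0.13 with day 14.

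**Figure D3:**
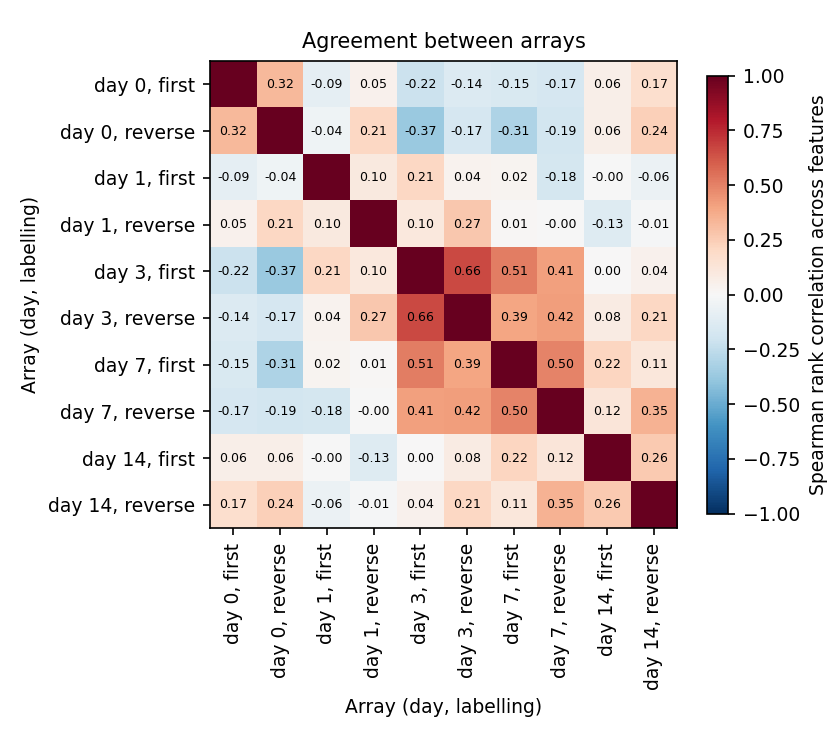
Spearman rank correlation across the 2300 features for each pair of the 10 arrays (both axes: day and labelling; colour scale from -1 to 1). The arrays of days 3 and 7 form the most alike set, and those of time 0 have values below 0 with them.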

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

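Of the tests below, the dye-bias, array-noise, time 0 sign and extreme-ratio tests were chosen after the result was seen, and the print-block tests were set before. Every difference between days comes from the array-level limma fit.

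Ratios differed between days 3 and 14. Between these days 173 features differed (99 up, 74 down), against 13 between days 3 and 7 and 18 between days 7 and 14, and 13 named genes were among the 173. Bckdk moved by 1.52, Neb by 1.48, Ddx42 by 1.27 and Zfp948 by 1.27 from day 3 to day 14. In the other direction Nisch moved by -1.37, Pcdh19 by -1.27, Gclm by -1.25, Maoa, a monoamine oxidase, by -1.13 and Larp4b by -1.10. Slc25a4 moved by -1.03, Irf1 by -1.03, Tmem263 by -0.88 and Msi2, an RNA-binding protein, by -0.73. These counts depended on single arrays. Without 1 day 3 array 20 or 30 features differed between days 3 and 14, and of the 13 named genes none or Neb alone was among them, while without 1 day 14 array 275 or 120 differed, with 10 or 5 of the 13. With print blocks centred 132 differed (115 up, 17 down), with 5 of the 13 (Bckdk, Ddx42, Zfp948, Pcdh19 and Neb). With each array centred on its median 194 differed (135 up, 59 down), with 11 of the 13. With repeated spot values left out 281 differed (153 up, 128 down), with all 13. The count of 18 between days 7 and 14 also depended on single arrays of both days. Its majority direction was up, turned to down without the reverse labelling of day 7 and stayed up without the first. With 1 day 14 array left out, the majority direction too turned with the labelling left in. It was up with the reverse labelling alone and down with the first alone, both for days 7 and 14 and for days 3 and 14. The test is of the difference, and of these genes Pcdh19 and Tmem263 were called in opposite directions on the 2 days. The adjusted p of these genes ran from 0.0231 (Zfp948) to 0.0449 (Irf1).

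Days 3 and 14 were less alike than days 3 and 7, and array noise alone is argued against as the cause, since correlations divided by the root of the swap correlations were 0.755 for days 3 and 7 and 0.201 for days 3 and 14, a difference of 0.554 (0.471 to 0.633). Print-block effects as the whole cause are argued against too, since the difference of mean rank correlations was 0.336 (0.305 to 0.367) with blocks centred. Dividing by the swap correlations allows only for the spread between the arrays of a day. Differences between days in the animals or RNA sampled are not removed by it, stay open and were not tested. A probe shift also present at time 0 remains open. Of the 160 unnamed probes among the 173, 78.8% (126 probes, exact binomial interval 71.6% to 84.8%) had at time 0 the sign of their day 14 minus day 3 difference, which contains day 3 and so partly restates that time 0 runs against day 3, while unnamed features called at days 14, 3 and 7 shared the time 0 sign in 60.4%, 36.3% and 30.2%. A change of programme between early and late denervation is a hypothesis. These arrays cannot separate it from such a shift, since by its label time 0 had no days of denervation behind it. They also cannot separate it from differences in the animals or RNA sampled at each day. The labels do not say whether the arrays of a day shared extracts or how many animals they covered.

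Time 0 ratios ran against those of days 3 and 7, with a mean rank correlation of -0.21. With print blocks centred it was -0.22 (-0.249 to -0.194), which argues against location effects as the whole cause. Dye bias, of single probes or varying with spot intensity, would turn sign between swapped arrays, and it is argued against as the whole cause since those of time 0 correlated at 0.32 (0.291 to 0.364). A shift between the 2 RNA samples that is not tied to the dye and a difference between the 2 legs before denervation stay open and were not tested.

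Many extreme ratios, of 3 or more in size, did not repeat on the swapped array, and 142 of 688 such probe values faced a probe there that held mostly the repeated value, so they were left out. Over all usable values 50.2% (274 of 546, 45.9% to 54.5%) had the same sign on both arrays. By day the shares were 87.1%, 19.6%, 70.4%, 62.3% and 28.6% at time 0 and days 1, 3, 7 and 14. At days 1 and 14 together the share was 26.9% (67 of 249, 21.5% to 32.9%), where the signs of the swapped arrays alone would give 45.5%. The days were grouped by these shares, so this gap cannot decide against defects of single spots. A labelling effect at single spots predicts such a share below 50%, and at these days the extremes were mostly negative on the first labelling (0 of 11 and 5 of 62 positive) and positive on the reverse (35 of 35 and 123 of 141), with 10 and 17 probes extreme on both arrays in opposite directions against 0 and 2 in the same. At time 0 and days 3 and 7 the share was 69.7% (207 of 297, 64.1% to 74.9%). The shares of days 3 and 7 argue against a labelling effect as the whole cause on those days. Extremes there were mostly positive on the first labelling (61 of 67 and 85 of 90) and on the reverse (13 of 14 and 56 of 64). At time 0, 61 of 62 usable extremes lay on the reverse labelling, all positive, with 0 extreme on both arrays. A labelling effect therefore stays open at time 0. Defects of single spots stay open and were not tested for these time points. The days were grouped after their shares were seen, probes are not independent, and no biological explanation was tested. A probe extreme on both arrays was counted once for each array, so the intervals of these shares are too narrow.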

How the results depend on the processing

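The settings of spot mean, spot agreement, repeated spot values, print-block centring and days 3 and 7 alone, and all those for array-level calls and for differences between days, were chosen after seeing the data. The mean of days 1 to 14 gave 0 calls under every alternative run, the replicate block included. The slope gave 52 calls with the time point as a random block over 10 arrays and 32 with the replicate block as well, and 0 otherwise. Late over early gave 1 call with the random block over 8 arrays, 0 with the replicate block, and 21 with spots within 2 log2 units, which tested 1285 features. The block fits count residual degrees of freedom over arrays and not over time points, so their p-values are likely too small. The replicate numbers mark labelling orientation, not animals, and differences between the swapped arrays correlated across days at 0.02 to 0.29. The cause was not tested for any change given here, except where the setting itself removes arrays, features or the sign condition. Large ratios at time 0 (67) went to 156 at 1.5-fold, 1 with each array at least 1, 114 with the mean of the 4 spots, 4 with spots within 2 log2 units, 21 with repeated spot values left out on any array and 0 with limma. At day 1 (60) they went to 3 with each array at least 1, 19 with arrays centred, 98 with time 0 subtracted, 3 with spots within 2 log2 units, 28 with print blocks centred, 6 with repeated spot values left out and 1 with limma. At day 3 (157) they went to 389 at 1.5-fold, 64 with each array at least 1, 303 with time 0 subtracted and 74 with spots within 2 log2 units. At day 7 (197) the same settings gave 493, 96, 353 and 89. At day 14 (259) they went to 568 at 1.5-fold, 101 with each array at least 1 and 115 with spots within 2 log2 units. With 1 array left out, large ratios ran from 29 to 95 at day 1, 216 to 322 at day 7 and 432 to 447 at day 14. Array-level calls with spots within 2 log2 units went to 10 at time 0, 5 at day 1, 407 at day 3 and 441 at day 7. With time 0 subtracted they went to 0 at day 1 and 92 at day 14, of which 91 were among the 329. With 1 array left out, the lone array being assumed to vary like the others, they ran from 5 to 10 at time 0, 0 to 1 at day 1, 36 to 53 at day 3 and 85 to 168 at day 7. At day 14 they ran from 261 to 327, and 133 and 142 of these were among the 329. With repeated spot values left out, array-level calls were 228, 324 and 403 at days 3, 7 and 14, and 181, 259 and 322 of the earlier calls were among them. Turning the sign of the reverse-labelled arrays moved Scn4b from -0.87 to 0.0525 and Mef2a from 0.57 to 0.0331 in the mean of days 1 to 14, against the direction the labels state. Of 196 values of called genes under alternatives, 133 kept the call and 63 kept direction but lost it. Mean, slope and late minus early values of genes had no call to lose, and 1, that of Scn4b, reversed. Features that differed between days 3 and 7 (13) went to 56 with spots within 2 log2 units and 20 with print blocks centred, and ran from 9 to 53 with 1 array left out. Those between days 7 and 14 (18) went to 311 with spots within 2 log2 units, 31 with repeated spot values left out and 10 with robust eBayes, and ran from 10 to 191 with 1 array left out. Those between days 3 and 14 (173) went to 429 with spots within 2 log2 units and 281 with repeated spot values left out, and ran from 20 to 275 with 1 array left out. No value was missing, so the planned setting with a value on at least 1 array changed nothing. List tests and their alternatives were not run, since no list had 5 measured members. Signal over background is unknown for these arrays, so low-signal spots could not be left out.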

Other observations

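Subtracting time 0, which also enlarges the standard error, lowered the number of array-level calls from 183 to 160 at day 3 and from 267 to 252 at day 7. Mef2a lost its day 7 call (limma, adjusted p = 0.0996), with a ratio of 0.89 against 0.92 before. Some named genes were called only after the subtraction. At day 3 minus time 0, Arf6, a small GTPase of membrane traffic, differed by 0.93 and Msi2 by 0.66 (limma, adjusted p = 0.0494 and 0.0485), beside Scn4b, Larp4b, Pcdh19 and Tmem263. Arf6 stood at -0.38 at time 0 and 0.55 at day 3, and Msi2 at -0.22 and 0.43. At day 7 minus time 0, Qtrt2, a subunit of the queuine tRNA transferase, differed by 0.77 and Tmem263 by 0.63 (limma, adjusted p = 0.0390 and 0.0467). Qtrt2 stood at -0.37 at time 0 and 0.40 at day 7. These genes were named after their values were seen.

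The unnamed probes held the widest ratios that repeated on both arrays. For spot_6412 the ratio was 3.83 ± 0.02 at day 3, 2.36 ± 0.63 at day 7 and 5.21 ± 0.11 at day 14 (SD, n = 2 arrays), after -0.02 at time 0. For spot_4134 it was -2.99 ± 0.22, -1.97 ± 0.19 and -2.27 ± 0.13. Over days 3, 7 and 14 together, 225 features were higher and 246 lower on all 6 arrays, against 35.9 each way by chance for independent arrays. The arrays of a time point are not independent, so 35.9 is a lower limit and the excess over it is overstated.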
